A study of Caenorhabditis elegans with 30 samples.

How the data were processed

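RNA from 30 populations of N2 worms had been hybridised to Affymetrix C. elegans Gene 1.0 ST arrays, 1 array per population. The populations form 6 groups of 5 biological replicates, an empty-vector control and an frh-1 RNAi arm at each of 3 ages. The values analysed are the deposited log2 signals per probe set, for which the authors name RMA, without a version. RMA by its definition corrects the background, quantile-normalizes the arrays and summarises probes on a log2 scale. The array medians of the deposited values differ a little, between 4.39 and 4.57. The settings of RMA are not known, and these medians do not tell them. Values run from 1.28 to 14.46 for 29317 probe sets. Array images, probe sequences and detection calls were not used here, so the precision rests on the 5 arrays per group.

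A list of probes paired 25600 probe sets with 1 gene symbol, 54 of them by repeating the same symbol, and left 3125 without a name. A further 592 probe sets carried several symbols and were left out with the unnamed ones. Where several probe sets named 1 gene, as for 61 genes, the probe set with the highest mean over all arrays was kept. This gave 25528 genes, namely 18850 protein-coding genes, 6030 noncoding RNA genes, 607 pseudogenes and 41 without a matched biotype. Identifiers of 25549 probe sets matched a RefSeq table of the WBcel235 assembly, and 51 did not. That table served for names, biotypes and the order of neighbouring genes. No symbol changed through it, and the 12 protein genes of the mitochondrial genome were matched through their alternative names. The deposited table states no genome build, so no coordinates are given.

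The 30 arrays entered 1 linear model per gene with 1 coefficient per group, fitted with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with version 1.17.8 of the data.table package. There were 11 contrasts, namely the RNAi effect at each age, its average over the 3 ages, its differences between ages, and the change with age within each arm. P values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05 and no fold threshold. Errors printed after ± beside log2 changes are the model's standard errors, and those beside levels are standard deviations of 5 arrays. The level of frh-1 was also compared by an exact two-sided permutation test of 5 against 5 arrays, whose smallest possible p is 0.0079. That test takes no account of replicate numbers.

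For 52 gene lists, limma's camera tested whether the members' changes differed from those of the other genes, with its preset inter-gene correlation of 0.01 and adjustment over the lists within a contrast. The test was repeated with a correlation estimated from the residuals. For every list the members past the gene-wise test were counted over all genes tested and adjusted over the list alone. The lists, the contrasts, the thresholds, the alternative settings and the rule for named genes were fixed before the data were examined. That rule takes frh-1 in every contrast. For each RNAi effect it takes the 10 largest rises and the 10 largest falls among genes past the threshold. All 5 arrays of each group had to lie on its own side of the other group's mean. By the same rule 8 rises and 8 falls are taken for each age change, and 5 in each direction for the averaged effect and each difference between ages, there without the condition on single arrays. In each list the members with the smallest p serve as examples.

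The code was tested on simulated data drawn from normal distributions with each gene's mean and residual standard deviation. For the day 7 RNAi contrast with 25528 genes, 41% of 100 genes changed by 0.5 on the log2 scale were recovered, and 94% of 100 genes changed by 1. Of the calls, 6% were unchanged genes. With no simulated change, 0 genes were called in the day 4 contrast. A list of 30 genes raised by 0.3 gave p = 3.51e-24 by camera with its preset correlation, and 30 unchanged genes gave p = 0.755. The simulated genes were drawn independently, so these list tests do not examine correlation between genes. Far fewer genes were changed than the 2887 called in the real day 7 contrast, which makes the adjusted threshold stricter. The shares recovered therefore do not give the power of that contrast.

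Replicate numbers could have marked shared cultures, so correlations of residuals between same-numbered arrays were compared with those between other arrays. Only between the 2 groups of day 7 did all 5 same-numbered pairs exceed 0.1, with correlations from 0.12 to 0.26 and a mean of 0.18 against -0.04 for other pairs. The numbers thus pair the arrays in that comparison, and the replicate number as a block was an alternative for every contrast. Between the 2 groups of day 14 they ran from 0.07 to 0.21, with a mean of 0.11 against -0.03. There, as at day 7, 9 arrays correlated best with their own number. Between successive ages within an arm the means were 0.09 to 0.14. A weaker pairing in these comparisons is not ruled out. With it the day 7 contrast gave 3261 genes, 2151 higher and 1110 lower.

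Alternative settings were the replicate block, removal of the dimmest 25% of genes, quantile normalization of the tested genes, subtraction of each array's median, a variance trend with intensity, array weights and a fit of only the groups compared. Further ones were the mean of a gene's probe sets, all probe sets, a fold threshold of 1.5, a threshold of 0.01, leaving out each array in turn, the estimated correlation and limma's fry in its directional form. Fry tests the members against no change, while camera compares them with the other genes, so the 2 answer different questions. Leaving out the 3 frh-1 RNAi arrays of replicate 5 was added after the data had been seen. For each count of genes, 100 splits of the arrays compared, the real one included, were fitted with group labels exchanged. For the day 7 effect the real split was set among the 16 that part all 5 pairs. For the 3 counts joining day 7 with other ages, 100 splits parting those pairs were drawn later and used in place of a first 100 without that limit, in which only the real split gave as many genes. Counts of list members under other settings, or with 1 array left out, are printed where a count of at least 3 moved by over 1.5 times.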

Results

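Transcript signals were measured in 30 populations of wild-type N2 Caenorhabditis elegans kept at 20 °C. Worms had fed over 3 generations on bacteria carrying either the empty vector pL4440 or a vector producing double-stranded RNA against frh-1. This gene encodes the worm frataxin, a mitochondrial protein of iron-sulfur cluster assembly. Both treatments were sampled at days 4, 7 and 14 with 5 biological replicates each. The labels conflict on the ages, because the series description counts days after birth and the treatment protocol counts days of adulthood. Correlations between arrays of the same group ran from 0.984 to 0.994. The 3 frh-1 RNAi arrays of replicate 5 had the highest means over all probe sets, 5.43 to 5.49, against 5.36 to 5.39 for the other 27 arrays.

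The frh-1 signal itself was not lower in the arrays labelled frh-1 RNAi at any age. At day 4 it was 6.89 ± 0.681 in these arrays and 6.49 ± 0.214 in controls (n = 5 each), a log2 difference of 0.40 ± 0.39 that did not pass the test (adjusted p = 0.891, exact permutation p = 0.24). At day 7 it was 9.01 ± 1.1 against 6.38 ± 0.868, 6.17-fold higher (adjusted p = 2.24e-05). At day 14 it was 12.04 ± 0.22 against 6.04 ± 0.359, 63.9-fold higher (adjusted p = 1.24e-11) and the largest rise of all 25528 genes. At both later ages each of the 5 labelled arrays lay above all controls, with an exact two-sided permutation p of 0.0079, the smallest that 5 against 5 arrays can give. That test exchanges labels freely. At day 7 replicate numbers pair the arrays, and only 16 splits part all 5 pairs, too few for a share under 0.05. At day 14, where numbers may pair arrays too, this p holds only if they do not. The day 14 level stood at percentile 99.2 of all genes, against 66.4 in controls. Because the signal of the targeted gene runs against the label, the arm is called the labelled RNAi arm here, and every direction is that of arrays so labelled relative to arrays labelled as control.

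**Figure D1:**
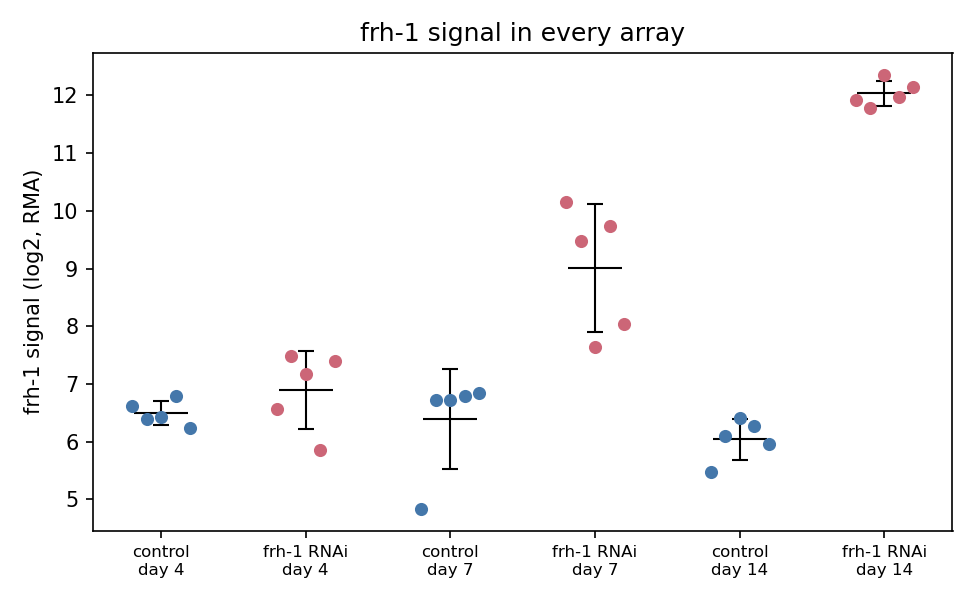
Signal of frh-1 (log2, vertical axis) in each of the 30 arrays by group (horizontal axis), with points for arrays, bars for means and error bars for standard deviations of 5 arrays. All 5 labelled RNAi arrays of day 14 lie between 11.79 and 12.36, while their controls lie between 5.47 and 6.40.

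At day 4 genes of xenobiotic metabolism were among those that rose most in the labelled RNAi arm. Among the cytochrome P450 enzymes, cyp-13A8 was 39.5-fold higher (log2 5.30 ± 0.22, n = 5 per group), cyp-14A4 rose by 4.91 ± 0.23, cyp-13A7 by 4.75 ± 0.22, cyp-33C8 by 3.93 ± 0.18 and cyp-13A12 by 3.57 ± 0.20. The cadmium-responsive genes cdr-4 and cdr-2 rose by 4.13 ± 0.15 and 3.78 ± 0.16, the C-type lectin clec-4 by 4.65 ± 0.27, B0205.13 by 4.90 ± 0.25 and F22B3.7 by 3.93 ± 0.30. The largest falls were in asm-3, an acid sphingomyelinase gene (-3.54 ± 0.39), pud-4 (-3.13 ± 0.33), the delta-9 desaturase gene fat-7 (-2.90 ± 0.43), the lysozyme genes lys-4 (-2.72 ± 0.26) and ilys-5 (-2.58 ± 0.37), F42A10.7 (-2.59 ± 0.51), pud-3 (-2.33 ± 0.30), oac-20 (-2.13 ± 0.18) and drd-50 (-2.03 ± 0.36). The infection response gene irg-5 fell by 2.37 ± 0.58 (adjusted p = 0.015), a call that was lost without frh-1 RNAi day 4 replicate 5 (adjusted p = 0.0592) and when only the arrays of day 4 were fitted (0.18). Across all genes 608 rose and 208 fell, of which 141 and 76 changed at least 2-fold.

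Of 24 measured genes of glycolysis and gluconeogenesis, 10 rose at day 4, 0 fell and 14 did not pass, with 13 rising when adjusted over the list alone (list adjusted p = 7.9e-14, adjusted p = 0.00718 with an estimated correlation). Examples are the glyceraldehyde-3-phosphate dehydrogenase gene gpd-2 (0.96 ± 0.11), the phosphoenolpyruvate carboxykinase gene pck-2 (0.59 ± 0.071), the glyoxylate cycle gene icl-1 (1.00 ± 0.14) and the aldolase gene aldo-1 (0.99 ± 0.15). In the tricarboxylic acid cycle 6 of 21 genes rose, among them dld-1 (0.31 ± 0.066), and 15 did not pass, with 9 rising when adjusted over the list alone (list adjusted p = 2.07e-07, adjusted p = 0.0381 with an estimated correlation). Of 74 cytochrome P450 genes 15 rose, 8 fell and 51 did not pass, 16 and 10 when adjusted over the list alone (list adjusted p = 0.000416, adjusted p = 0.0439 with an estimated correlation). The median over P450 genes was 0.06 and their mean 0.41. In the metallothionein and cadmium response list cdr-4 and cdr-2 rose, the metallothionein genes mtl-1 (-1.22 ± 0.31) and mtl-2 (-0.74 ± 0.19) fell, and 5 of 9 did not pass, 3 rising and 2 falling when adjusted over the list alone (list adjusted p = 0.00282, adjusted p = 0.0381 with an estimated correlation). The call of mtl-1 was lost without replicate 3 or 5 of either arm (adjusted p = 0.0582 to 0.0882). That of mtl-2 was lost without control replicate 2, 3 or 5 or labelled RNAi replicate 1, 2 or 3 (0.0583 to 0.105). Of 8 lysosomal lipase genes, lipl-5 (-1.21 ± 0.19), lipl-1 (-1.14 ± 0.21) and lipl-2 (-0.68 ± 0.20) fell and 5 did not pass, also 3 falling when adjusted over the list alone (list adjusted p = 0.00282, adjusted p = 0.0439 with an estimated correlation). The lipl-2 call held when control replicate 3 or labelled RNAi replicate 4 was the array left out, and was lost without any of the other 8 (0.0526 to 0.195). With the replicate block it had 0.0587, and in a fit of the day 4 arrays alone lipl-2 had 0.0569 and mtl-2 0.0828. The 6 rises of the tricarboxylic acid cycle were 2 without control replicate 3 and after subtracting array medians, 3 without the replicate 5 arrays and 1 in the fit of day 4 alone. The 8 P450 falls were 4 without control replicate 1 and 5 without the replicate 5 arrays.

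Other lists passed at day 4 with the preset correlation alone. Of the 12 protein genes of the mitochondrial genome, COX3 (0.57 ± 0.11), ATP6 (0.74 ± 0.16) and ND3 (0.88 ± 0.20) rose and 9 did not pass, 7 rising when adjusted over the list alone (list adjusted p = 1.73e-07, adjusted p = 0.221 with an estimated correlation). In the mitochondrial unfolded protein response list 3 of 16 genes rose and 13 did not pass, 9 rising when adjusted over the list alone (list adjusted p = 0.000109, adjusted p = 0.112 with an estimated correlation). The 3 were timm-23 (0.57 ± 0.12), dnj-10 and lonp-1. The dnj-10 call was lost without control replicate 1, 4 or 5 or labelled RNAi replicate 5 (adjusted p = 0.0541 to 0.11), and that of lonp-1 without control replicate 3 or 5 or labelled RNAi replicate 1, 2 or 5 (0.052 to 0.103). Both calls were also lost after subtracting array medians (0.0814 for dnj-10 and 0.127 for lonp-1) and in a fit of the day 4 arrays alone (0.0974 and 0.183). The list's 3 rises were 1 without the 3 replicate 5 arrays too. The mitochondrial chaperone genes hsp-6 (0.19 ± 0.062, adjusted p = 0.104) and hsp-60 (0.07 ± 0.069, adjusted p = 0.878) did not pass. Glutathione S-transferases and SKN-1 targets had 5 rises and 44 genes that did not pass, with 5 rises and 1 fall when adjusted over the list alone (list adjusted p = 0.00304, adjusted p = 0.106 with an estimated correlation). Examples are gst-14 (1.86 ± 0.23), gst-6 (1.75 ± 0.22) and the oxidative stress reporter gene gst-4 (1.42 ± 0.20). Among 66 lysozyme, saposin-like and pathogen response genes 4 rose, 16 fell and 46 did not pass, 8 and 17 when adjusted over the list alone (list adjusted p = 3.39e-05, adjusted p = 0.0791 with an estimated correlation). Examples are irg-8 (-1.98 ± 0.29) and lys-4 at -2.72 ± 0.26. The 4 rises were 2 without labelled RNAi replicate 5 and in the fit of day 4 alone. Of 150 neuropeptide genes 16 rose, 0 fell and 134 did not pass, 30 rising when adjusted over the list alone (list adjusted p = 1.29e-07, adjusted p = 0.112 with an estimated correlation). The first by p was ins-23 (1.34 ± 0.23). The 16 neuropeptide rises were 8 without labelled RNAi replicate 5, 9 after quantile normalization and 10 after subtracting array medians. Of 8 iron-sulfur cluster assembly genes, with a median of 0.22, 8 did not pass limma's test over all genes and 3 rose when adjusted over the list alone (list adjusted p = 0.00409, adjusted p = 0.188 with an estimated correlation). Of the 28 list calls at day 4, 5 held with an estimated correlation.

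At day 7 the labelled RNAi arm differed from control in 2887 genes, 1965 higher and 922 lower. The largest rises were in F22B3.7 (3.86 ± 0.30, from a control level of 3.08 not known to lie above background), the cuticle collagen genes col-94 (3.75 ± 0.47), col-125 (3.63 ± 0.69) and col-10 (3.12 ± 0.37), B0205.13 (3.33 ± 0.25), cyp-13A7 (3.31 ± 0.22), the UDP-glucuronosyltransferase gene ugt-2 (3.27 ± 0.21), tts-2 (3.26 ± 0.42), the C-type lectin clec-10 (3.08 ± 0.24) and chca-1 (3.02 ± 0.20), with n = 5 per group. The largest falls were in the short-chain dehydrogenase gene dhs-26 (-3.54 ± 0.39), the fatty acid and retinol binding gene far-3 (-3.39 ± 0.31), C17H12.8 (-3.29 ± 0.44), C30G12.2 (-3.16 ± 0.33), cyp-14A3 (6.22 in controls and 3.13, likewise not known to lie above background, in the labelled RNAi arm), F48C1.9 (-2.97 ± 0.24), the infection response gene irg-4 (-2.93 ± 0.35), ilys-5 (-2.75 ± 0.37), the lipase-related gene lips-11 (-2.68 ± 0.37) and col-183 (-2.67 ± 0.20). At least 2-fold changes numbered 437 higher and 99 lower. The balance of directions depended on scaling, with 1648 higher and 1575 lower after quantile normalization, 1643 and 1241 after subtracting array medians, and 1782 and 1337 without the 3 labelled RNAi arrays of replicate 5.

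Of 23 intestine markers 14 rose at day 7, 3 fell and 6 did not pass, 15 and 4 when adjusted over the list alone (list adjusted p = 7.88e-11, adjusted p = 0.0486 with an estimated correlation). They included the acid phosphatase gene pho-1 (2.19 ± 0.21), the proton pump subunit gene vha-6 (1.99 ± 0.20), the exchanger gene nhx-2 (1.35 ± 0.15) and the protease gene asp-1 (1.66 ± 0.19). Of 26 synaptic and neuronal markers 13 rose and 13 did not pass, 15 rising when adjusted over the list alone (list adjusted p = 3.47e-09, adjusted p = 0.0486 with an estimated correlation). Examples are the neuropeptide processing genes egl-3 (0.91 ± 0.11) and egl-21 (0.63 ± 0.095) and the vesicle release genes unc-18 (0.91 ± 0.11) and rab-3 (0.84 ± 0.12). Of 18 vacuolar ATPase genes 15 rose, 2 fell and 1 did not pass, also 15 and 2 when adjusted over the list alone (list adjusted p = 7.59e-13, adjusted p = 0.0513 with an estimated correlation). Germline and oocyte markers gave 0 rises and 12 falls in 33 genes, with 1 rise and 24 falls when adjusted over the list alone (list adjusted p = 3.84e-10, adjusted p = 0.0513 with an estimated correlation). Examples are glh-2 (-0.51 ± 0.083) and htp-3 (-0.35 ± 0.075). These 12 falls were 3 in a fit of the day 7 arrays alone and 20 with a variance trend. Pharyngeal markers had 22 rises, 1 fall and 43 genes that did not pass, 27 and 2 when adjusted over the list alone (list adjusted p = 5.73e-07, adjusted p = 0.0513 with an estimated correlation), and tnc-2 stood at 0.92 ± 0.15. Neuropeptide genes had 57 rises, 6 falls and 87 that did not pass, 62 and 8 when adjusted over the list alone (list adjusted p = 4.97e-11, adjusted p = 0.0567 with an estimated correlation), and the insulin-like genes ins-23 (2.68 ± 0.23) and ins-7 (1.43 ± 0.15) were among them. The 6 neuropeptide falls were 3 without labelled RNAi replicate 3.

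Among respiratory chain genes at day 7, the nuclear genes of complexes II to V had 15 rises and 21 not passing, 19 rising when adjusted over the list alone (list adjusted p = 2.61e-08, adjusted p = 0.0567 with an estimated correlation). The complex III core gene ucr-2.1 stood at 1.04 ± 0.097 and the ATP synthase genes asb-2 and asg-2 at 0.85 ± 0.10 and 0.81 ± 0.13. The 15 rises were 8 without control replicate 5 and after subtracting array medians, and 7 in a fit of the day 7 arrays alone. In complex I, 4 of 26 genes rose and 22 did not pass, 6 rising when adjusted over the list alone (list adjusted p = 2.34e-05, adjusted p = 0.24 with an estimated correlation), the first being gas-1 (0.63 ± 0.12). Only 1 of complex I rose without control replicate 5, after subtracting array medians or in the fit of day 7 alone, where nduf-11, nduf-7 and nuo-2 lost their calls. Of the mitochondrial genome genes 4 of 12 rose and 8 did not pass, 6 rising when adjusted over the list alone (list adjusted p = 0.000569, adjusted p = 0.441 with an estimated correlation), ND3 among them (0.94 ± 0.20). Only 1 of these rose without labelled RNAi replicate 5, where COX3 (adjusted p = 0.115), ND6 (0.0757) and ND4L (0.0502) lost their calls, and 2 without all 3 replicate 5 arrays. Fry, a test against no change, did not call that list at day 7 (adjusted p = 0.0584). In the propionate shunt and vitamin B12 list 8 of 18 rose and 10 did not pass, 9 rising when adjusted over the list alone (list adjusted p = 0.000416, adjusted p = 0.0567 with an estimated correlation). Examples are nhr-114 (1.43 ± 0.17), alh-8 (0.63 ± 0.08), hphd-1 (1.56 ± 0.22) and acdh-1 (2.34 ± 0.46). Of 67 UDP-glucuronosyltransferase genes 18 rose, 7 fell and 42 did not pass, 21 and 9 when adjusted over the list alone (list adjusted p = 0.000107, adjusted p = 0.191 with an estimated correlation). Examples are ugt-62 (2.67 ± 0.16) and ugt-19 (2.63 ± 0.18), and the 7 falls were 4 without the replicate 5 arrays. The P450 list, with 13 rises, 16 falls and 45 not passing (15 and 18 adjusted over the list alone), did not pass (list adjusted p = 0.503), and its median (-0.07), mean (0.03) and test direction (down) differed in sign, the mean falling to -0.03 after quantile normalization and -0.02 after subtracting array medians.

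Of 170 cuticle collagens 44 rose at day 7, 2 fell and 124 did not pass, 55 and 2 when adjusted over the list alone (list adjusted p = 2.4e-11, adjusted p = 0.169 with an estimated correlation). Larval molting markers, which mark another stage, had 7 rises and 15 genes not passing, 9 rising when adjusted over the list alone (list adjusted p = 9.42e-07, adjusted p = 0.24 with an estimated correlation). Examples are the hedgehog-related gene wrt-2 at 2.02 ± 0.40 and qua-1 at 1.05 ± 0.16. The centred mean of the cuticle collagens was 0.78 in replicate 5 of the labelled RNAi arm and 0.19 to 0.27 in its other 4 arrays, and 33 of the 44 rises were kept without the replicate 5 arrays. At day 4 the same list had 0 rises and 6 falls among 170, led by col-43 (-1.75 ± 0.23), 1 and 7 when adjusted over the list alone (list adjusted p = 0.0217, adjusted p = 0.642 with an estimated correlation). That day 4 call was also lost after quantile normalization (0.0715), after subtracting array medians (0.0516) and without the replicate 5 arrays (0.0939), and fry gave 0.627.

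At day 14 the labelled RNAi arm showed higher levels of HIF-1 targets, a fixed list of genes linked to the hypoxia-inducible factor HIF-1. Of 14 such genes 9 rose, 0 fell and 5 did not pass, 12 rising when adjusted over the list alone, with a median of 0.75 (list adjusted p = 2.96e-16, adjusted p = 0.000179 with an estimated correlation). The cysteine synthase-like gene cysl-2 rose by 1.99 ± 0.14, the regulator gene rhy-1 by 1.45 ± 0.15, the flavin monooxygenase gene fmo-2 by 2.74 ± 0.29 and the nuclear receptor gene nhr-57 by 1.58 ± 0.21 (n = 5 per group). The list did not pass at day 4 (2 rises among 14, 3 adjusted over the list alone, list adjusted p = 0.184) or day 7 (4 rises and 1 fall, 5 and 1 adjusted over the list alone, list adjusted p = 0.572). The 4 rises of day 7 were 1 without labelled RNAi replicate 3 and 2 after quantile normalization. The 1 fall of day 7 was ftn-1. Whether HIF-1 raises each member was not tested, and the list scores ftn-1 like the others. The end of its fall by day 14 therefore adds to the list's difference between these ages. Besides frh-1, the largest single rises were in col-161 (3.63 ± 0.75), col-125 (3.44 ± 0.69), clec-52 (3.31 ± 0.21), the propionate shunt gene acdh-1 (3.13 ± 0.46), rol-1 (3.08 ± 0.76), col-73 (2.96 ± 0.63), col-162 (2.83 ± 0.69), col-145 (2.80 ± 0.53) and col-38 (2.77 ± 0.70). The largest falls were in C17H12.8 (-2.08 ± 0.44), the aspartyl protease gene asp-17 (-1.91 ± 0.28), the saposin-like gene spp-9 (-1.78 ± 0.41), the carnitine palmitoyltransferase gene cpt-3 (-1.77 ± 0.23), lips-11 (-1.63 ± 0.37), W03F9.4 (-1.57 ± 0.18), ilys-2 (-1.48 ± 0.25), F48C1.9 (-1.34 ± 0.24) and F53H4.2 (-1.34 ± 0.31). In all, 1529 genes rose and 467 fell, 301 and 26 at least 2-fold.

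Fitted on the 10 arrays of day 14 alone, 1136 genes passed, and the calls of col-161, rol-1, col-73, col-162, col-145, col-38 and F53H4.2 were lost (adjusted p = 0.0509 to 0.109). The fall of nspg-7.2 (-1.64 ± 0.49, adjusted p = 0.0361) was kept only when control replicate 2 or 5 or labelled RNAi replicate 5 was the array left out, and was lost without any of the other 7 (0.0567 to 0.133). After quantile normalization 1353 genes were higher and 1080 lower.

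Metabolic lists held at day 14 with an estimated correlation. Of 36 genes of respiratory complexes II to V 19 rose and 17 did not pass, 26 rising when adjusted over the list alone (list adjusted p = 9.98e-17, adjusted p = 0.00278 with an estimated correlation). Examples are ucr-2.1 (0.92 ± 0.097), asb-2 (0.83 ± 0.10) and the succinate dehydrogenase gene sdha-1 (0.58 ± 0.088). In the tricarboxylic acid cycle 12 of 21 rose and 9 did not pass, with 13 rises and 1 fall when adjusted over the list alone (list adjusted p = 2.05e-09, adjusted p = 0.00533 with an estimated correlation). Examples are idhb-1 (0.61 ± 0.077) and the citrate synthase gene cts-1 (0.49 ± 0.063). In glycolysis and gluconeogenesis 13 of 24 rose and 11 did not pass, 17 rising when adjusted over the list alone (list adjusted p = 9.62e-16, adjusted p = 0.00141 with an estimated correlation). Examples are gpd-2 (1.00 ± 0.11), ldh-1 (0.91 ± 0.12) and pck-1 (0.88 ± 0.12). In the propionate shunt and vitamin B12 list 10 of 18 rose and 8 did not pass, 12 rising when adjusted over the list alone (list adjusted p = 1.38e-11, adjusted p = 0.000588 with an estimated correlation). Examples are nhr-68 at 1.79 ± 0.19 and hphd-1 at 1.53 ± 0.22. Of 23 intestine markers 14 rose and 9 did not pass, 15 rising when adjusted over the list alone (list adjusted p = 9.98e-17, adjusted p = 0.00239 with an estimated correlation). Examples are pho-1 (1.84 ± 0.21), vha-6 (1.73 ± 0.20) and the intestinal GATA factor gene elt-2 (1.14 ± 0.15). In complex I 7 of 26 rose, 11 when adjusted over the list alone (list adjusted p = 9.05e-08, adjusted p = 0.149 with an estimated correlation), 2 without control replicate 1 and 4 after subtracting array medians. In the fit of day 14 alone the rises were 2 in complex I, 4 in the tricarboxylic acid cycle, 8 in glycolysis and gluconeogenesis and 6 in the propionate shunt list.

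Several further lists passed at day 14 only with the preset correlation. Cuticle collagens had 55 rises and 3 falls among 170, 74 and 6 when adjusted over the list alone (list adjusted p = 2.39e-12, adjusted p = 0.137 with an estimated correlation). Examples are col-178 (1.39 ± 0.17) and col-7 (1.48 ± 0.22), and 52 of the 55 were kept without the replicate 5 arrays. In the fit of day 14 alone 22 collagens rose and 0 fell, and 0 fell without control replicate 2. Of 12 mitochondrial genome genes 4 rose and 8 did not pass, 8 rising when adjusted over the list alone (list adjusted p = 5.39e-05, adjusted p = 0.437 with an estimated correlation), ND3 again at 0.91 ± 0.20 and ATP6 at 0.72 ± 0.16. Fry did not call it (adjusted p = 0.0519). The 4 rises were 2 in the fit of day 14 alone and 7 with the replicate block or without labelled RNAi replicate 4. Vacuolar ATPase genes had 10 rises and 8 not passing, 15 rising when adjusted over the list alone (list adjusted p = 1.39e-09, adjusted p = 0.093 with an estimated correlation). These 10 were 2 without control replicate 5 and in the fit of day 14 alone, 5 after quantile normalization and 6 after subtracting array medians. Of 67 UDP-glucuronosyltransferase genes 21 rose, 2 fell and 44 did not pass, 28 and 3 when adjusted over the list alone (list adjusted p = 2.62e-09, adjusted p = 0.0524 with an estimated correlation). The first by p was ugt-47 (2.38 ± 0.23). Body wall muscle genes had 9 rises and 20 not passing, 13 and 2 when adjusted over the list alone (list adjusted p = 5.39e-05, adjusted p = 0.329 with an estimated correlation). An example is the troponin T gene tnt-3 at 0.95 ± 0.15. The 9 rises were 2 in the fit of day 14 alone, 4 without labelled RNAi replicate 1 and 14 without its replicate 4. Of 28 sperm markers 5 rose, among them msp-78 (2.63 ± 0.47), nspd-1 (2.72 ± 0.51) and msp-38 (1.37 ± 0.26), and 23 did not pass, 6 when adjusted over the list alone (list adjusted p = 0.0114, adjusted p = 0.324 with an estimated correlation). The mitochondrial unfolded protein response list, with 2 rises among 16, also 2 adjusted over the list alone, did not pass (list adjusted p = 0.251). Nor did the 12 measured heat shock genes, with 1 rise and 2 adjusted over the list alone (list adjusted p = 0.0624). Another 6 genes of that list were not measured, namely hsp-16.1, hsp-16.11, hsp-16.48, hsp-16.49, F44E5.4 and F44E5.5. The heat shock response list did pass with array weights (0.0253) and without the replicate 5 arrays (0.0156), and by fry, a test against no change (0.0199).

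**Figure D2:**
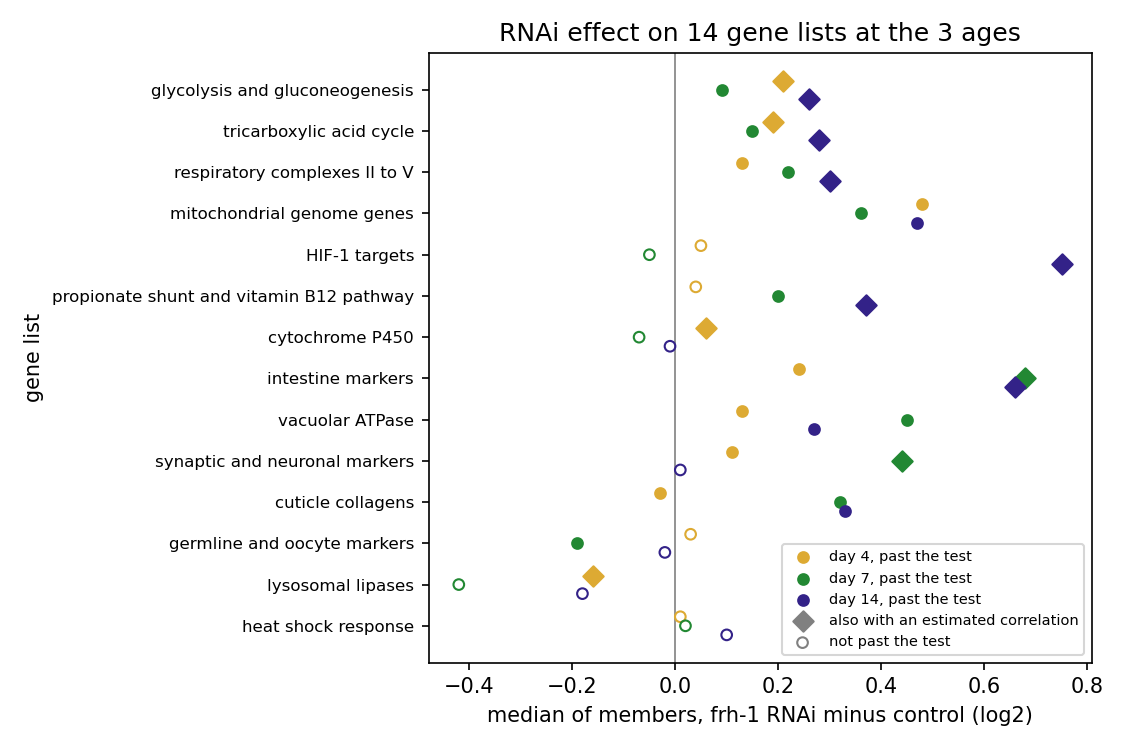
Median log2 change of the members of 14 gene lists (horizontal axis, labelled RNAi arm minus control) at days 4, 7 and 14. Filled symbols mark lists past the test and diamonds those also past it with an estimated correlation. HIF-1 targets stand at 0.75 at day 14, against 0.05 at day 4 and -0.05 at day 7.

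Averaged over the 3 ages, 2616 genes were higher and 1020 lower in the labelled RNAi arm. The largest rises were in F22B3.7 (3.18 ± 0.18), clec-4 (3.13 ± 0.15), cyp-13A8 (3.03 ± 0.13), frh-1 (3.01 ± 0.23) and B0205.13 (2.94 ± 0.14), and the largest falls in C17H12.8 (-2.46 ± 0.26), dhs-26 (-2.13 ± 0.23), asm-3 (-2.12 ± 0.22), ilys-5 (-1.95 ± 0.22) and C30G12.2 (-1.85 ± 0.19), with n = 15 arrays per arm. Of 25 antioxidant enzyme genes 9 rose and 16 did not pass, 10 and 1 when adjusted over the list alone (list adjusted p = 0.000246, adjusted p = 0.0449 with an estimated correlation). Examples are the mitochondrial thioredoxin gene trx-2 (0.49 ± 0.057), msra-1 (0.71 ± 0.087) and gpx-3 (0.82 ± 0.11). Vacuolar ATPase genes had 16 rises and 2 not passing, 16 and 1 when adjusted over the list alone (list adjusted p = 1.47e-13, adjusted p = 0.0289 with an estimated correlation). Pharyngeal markers had 24 rises, 1 fall and 41 not passing, 29 and 2 when adjusted over the list alone (list adjusted p = 5.16e-07, adjusted p = 0.0299 with an estimated correlation). The lysosomal lipase genes lipl-5 (-0.98 ± 0.11), lipl-2 (-0.84 ± 0.11) and lipl-1 (-0.69 ± 0.12) fell and 5 did not pass, also 3 adjusted over the list alone (list adjusted p = 0.00511, adjusted p = 0.034 with an estimated correlation). After quantile normalization 2205 genes were higher and 2222 lower, and after subtracting array medians 2220 and 1513.

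The effects at the 3 ages overlapped. Days 4 and 7 shared 402 rises against 46.8 expected for independent calls, and 81 falls against 7.51. Days 7 and 14 shared 718 rises against 118 and 74 falls against 16.9, and days 4 and 14 shared 285 rises against 36.4 and 15 falls against 3.81. At all 3 ages 230 genes rose and 11 fell. Across the 25528 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.48 for days 4 and 7 (Spearman's rho 0.27), 0.46 for days 7 and 14 (0.28) and 0.27 for days 4 and 14 (0.20).

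Differences between ages were tested directly. A positive difference includes a fall that became smaller, as in asm-3 (-3.54 at day 4 and -0.30 at day 14), and a negative one a rise that became smaller. The largest negative differences between day 14 and day 4 were in cyp-13A7 (-4.70 ± 0.31), B0205.13 (-4.33 ± 0.35), cyp-13A8 (-4.32 ± 0.31), cyp-14A4 (-4.07 ± 0.33) and cdr-4 (-3.81 ± 0.21). The largest positive differences were in frh-1 (5.60 ± 0.55), C14C6.5 (3.96 ± 0.55), clec-52 (3.52 ± 0.29), pud-4 (3.37 ± 0.47) and asm-3 (3.24 ± 0.55). In all, 398 genes had a positive and 190 a negative difference. HIF-1 targets had 5 positive differences and 9 not passing, 9 positive when adjusted over the list alone (list adjusted p = 5.69e-13, adjusted p = 0.000827 with an estimated correlation). Examples are rhy-1 (1.55 ± 0.21) and cysl-2 (1.32 ± 0.20). P450 genes had 2 positive and 12 negative differences, 5 and 16 when adjusted over the list alone (list adjusted p = 0.000196, adjusted p = 0.0347 with an estimated correlation). Intestine markers had 7 positive differences and 1 negative, 13 and 2 when adjusted over the list alone (list adjusted p = 7.44e-10, adjusted p = 0.0347 with an estimated correlation). An example is the cathepsin gene cpr-4 at 2.07 ± 0.23. The propionate shunt and vitamin B12 list had 4 positive differences, 7 when adjusted over the list alone (list adjusted p = 5.17e-08, adjusted p = 0.00585 with an estimated correlation). An example is nhr-68 at 1.57 ± 0.26. These 4 were 2 without the replicate 5 arrays and in a fit of the compared groups alone.

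Between day 4 and day 7 the difference was positive in 274 genes and negative in 171. The largest positive ones were in col-94 (3.52 ± 0.67), B0024.4 (3.00 ± 0.43), col-160 (2.79 ± 0.50), F42A10.7 (2.69 ± 0.71) and tts-2 (2.67 ± 0.60), and the largest negative ones in cyp-14A3 (-3.01 ± 0.39), far-3 (-2.94 ± 0.44), F48C1.9 (-2.74 ± 0.34), col-183 (-2.73 ± 0.28) and cyp-13A8 (-2.49 ± 0.31). The F42A10.7 difference (adjusted p = 0.0468) was kept when control day 4 replicate 3, control day 7 replicate 2 or 5, frh-1 RNAi day 4 replicate 4 or frh-1 RNAi day 7 replicate 2 was the array left out. It was lost without any of the other 15 arrays (0.0564 to 0.0952), after quantile normalization (0.0555) and after subtracting array medians (0.054). For frh-1 the difference was 2.22 ± 0.55 (adjusted p = 0.0299). That call was lost without control day 4 replicate 4, control day 7 replicate 1, frh-1 RNAi day 4 replicate 1 or 4, or frh-1 RNAi day 7 replicate 1, 2 or 4 (0.0536 to 0.0636), and in a fit of the compared groups alone (0.0798). Intestine markers had 6 positive differences and 1 negative, 12 and 2 when adjusted over the list alone (list adjusted p = 2.52e-09, adjusted p = 0.0467 with an estimated correlation), and 10 were positive after quantile normalization, with array weights or with a variance trend. P450 genes had 10 negative differences, 22 when adjusted over the list alone (list adjusted p = 6.87e-08, adjusted p = 0.00462 with an estimated correlation). With array weights 755 genes passed in place of 445.

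Between day 7 and day 14 the difference was positive in 353 genes and negative in 381. The largest positive ones were in irg-4 (3.42 ± 0.49), frh-1 (3.37 ± 0.55), C14C6.5 (3.33 ± 0.55), cyp-14A3 (2.79 ± 0.39) and clec-52 (2.56 ± 0.29), and the largest negative ones in cyp-13A7 (-3.26 ± 0.31), B0205.13 (-2.76 ± 0.35), B0024.4 (-2.70 ± 0.43), tts-2 (-2.70 ± 0.60) and acdh-2 (-2.55 ± 0.32). HIF-1 targets had 6 positive differences and 8 not passing, 12 positive when adjusted over the list alone (list adjusted p = 1.28e-12, adjusted p = 0.000848 with an estimated correlation). Examples are cysl-2 (1.49 ± 0.20) and the sulfide oxidation gene sqrd-1 (1.02 ± 0.22). Synaptic and neuronal markers had 4 negative differences, 8 when adjusted over the list alone (list adjusted p = 8.03e-09, adjusted p = 0.0268 with an estimated correlation). Examples are unc-18 (-0.86 ± 0.16) and rab-3 (-0.79 ± 0.17). The other 2, unc-13 and unc-64, lost their calls without control day 7 replicate 2 (adjusted p = 0.0829 and 0.0564), control day 14 replicate 1 (0.0754 and 0.0578) or frh-1 RNAi day 7 replicate 2 (0.0547 and 0.0522) and after subtracting array medians (0.0706 each). The unc-13 call was lost without any of 15 single arrays. Without frh-1 RNAi day 7 replicate 3 the count of 734 genes fell to 459, and without control day 14 replicate 1 to 484.

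**Figure D3:**
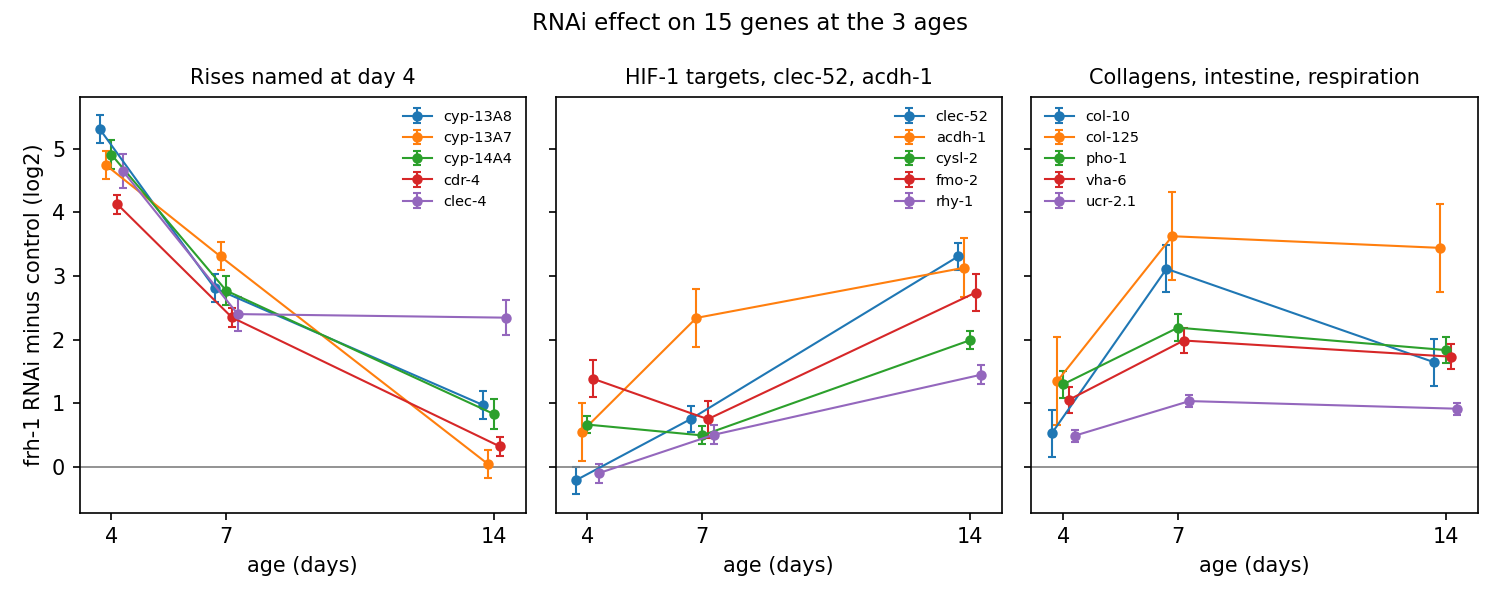
Labelled RNAi arm minus control (log2, vertical axis, error bars are standard errors) for 15 genes against age in days. The effect on cdr-4 goes from 4.13 at day 4 to 0.33 at day 14, and that on clec-52 from -0.21 to 3.31.

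In control worms from day 4 to day 7 the largest rises were in far-3 (24.9-fold, 4.64 ± 0.31), F15B9.6 (4.44 ± 0.23), mbug-1 (4.23 ± 0.37), lips-11 (18.4-fold), C50F7.5 (3.95 ± 0.32), F20G2.1 (3.65 ± 0.35), F56D6.8 (3.53 ± 0.28) and the lysozyme gene lys-7 (3.40 ± 0.30), with n = 5 per group. The largest falls were in pud-3 (-3.49 ± 0.30), mnp-1 (-3.39 ± 0.23), the homeobox gene ceh-36 (-3.35 ± 0.19), col-93 (-3.34 ± 0.56), M03D4.4 (-3.20 ± 0.19), col-20 (-3.18 ± 0.24), T02E9.5 (-3.17 ± 0.23) and col-92 (-3.04 ± 0.42). In all 2135 genes rose and 1885 fell. Of 29 body wall muscle genes 22 fell, with 0 rises and 7 not passing, 25 when adjusted over the list alone (list adjusted p = 9.05e-17, adjusted p = 0.0346 with an estimated correlation). Examples are the troponin genes tnt-3 (-1.07 ± 0.15) and tni-3 (-0.76 ± 0.11). Embryo markers had 2 rises, 12 falls and 10 not passing, 2 and 14 when adjusted over the list alone (list adjusted p = 2.43e-07, adjusted p = 0.0333 with an estimated correlation). Examples are pha-4 (-2.25 ± 0.18) and end-1 (-1.53 ± 0.17). Targets of the FOXO factor DAF-16 had 11 rises and 14 not passing, 12 when adjusted over the list alone (list adjusted p = 7.51e-07, adjusted p = 0.0316 with an estimated correlation). Examples are hil-1 (1.89 ± 0.14) and mtl-1 (2.63 ± 0.31). P450 genes had 20 rises, 5 falls and 49 not passing, 27 and 6 when adjusted over the list alone (list adjusted p = 0.000374, adjusted p = 0.035 with an estimated correlation). The 5 falls were 3 without control day 7 replicate 1 and 2 in a fit of the compared groups alone. Cuticle collagens had 2 rises, 39 falls and 129 not passing, 2 and 41 when adjusted over the list alone (list adjusted p = 7.51e-07, adjusted p = 0.455 with an estimated correlation).

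From day 7 to day 14 the controls changed in 7292 genes, 3207 rising and 4085 falling. Genes of the biotype ncRNA, without the other noncoding classes, made up 335 of the rises and 126 of the falls. Noncoding RNA genes of all classes were 6030 of the 25528 tested. T24A6.7 rose 22.6-fold, followed by R03H10.6 (4.02 ± 0.20), C54F6.15 (3.59 ± 0.19), the acyl-CoA synthetase gene acs-2 (11.3-fold), dma-1 (3.48 ± 0.26), T09F5.12 (3.44 ± 0.19), the RNA-dependent RNA polymerase gene rrf-2 (3.39 ± 0.14) and F43C1.7 (3.38 ± 0.27). The immune response genes sysm-1 (-4.26 ± 0.40), irg-4 (-3.90 ± 0.35), dod-24 (-3.88 ± 0.40) and spp-17 (-3.70 ± 0.26), mbug-1 (-3.78 ± 0.37), acdh-1 (-3.49 ± 0.46), the yolk protein gene vit-4 (-3.48 ± 0.38) and C17H12.6 (-3.37 ± 0.32) fell most. All 5 measured vitellogenins fell, also adjusted over the list alone (list adjusted p = 8.06e-05, adjusted p = 0.0421 with an estimated correlation), while vit-3 was not measured. Germline and oocyte markers had 26 falls and 7 not passing, 28 when adjusted over the list alone (list adjusted p = 4.94e-13, adjusted p = 0.0421 with an estimated correlation). Examples are mex-6 (-0.52 ± 0.056) and oma-1 (-0.59 ± 0.065). Synaptic and neuronal markers had 17 rises, 1 fall and 8 not passing, 19 and 1 when adjusted over the list alone (list adjusted p = 4.44e-08, adjusted p = 0.0421 with an estimated correlation). Examples are unc-13 (1.32 ± 0.11) and unc-64 (0.89 ± 0.089). Of 66 lysozyme, saposin-like and pathogen response genes 10 rose, 33 fell and 23 did not pass, 11 and 33 when adjusted over the list alone (list adjusted p = 2.65e-05, adjusted p = 0.0696 with an estimated correlation). Intracellular pathogen response genes had 23 rises, 3 falls and 23 not passing, the same counts of 23 and 3 when adjusted over the list alone (list adjusted p = 2.48e-07, adjusted p = 0.0848 with an estimated correlation). Examples are cul-6 (1.48 ± 0.15) and eol-1 (1.67 ± 0.19), and the 3 falls were 1 without control day 7 replicate 3.

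In the labelled RNAi arm 1270 genes rose and 1084 fell from day 4 to day 7. The largest rises were in B0024.4 (27.2-fold, 4.76 ± 0.31), C54C8.12 (13.9-fold), asp-17 (3.63 ± 0.28), lys-7 (3.58 ± 0.30), C50F7.5 (3.17 ± 0.32), C01G10.5 (3.16 ± 0.36), T22B7.7 (2.84 ± 0.20) and cpr-4 (2.83 ± 0.16), and the largest falls in clec-4 (-2.87 ± 0.27), T16G1.6 (-2.58 ± 0.23), cyp-13A8 (-2.48 ± 0.22), pud-3 (-2.45 ± 0.30), pax-3 (-2.42 ± 0.22), ceh-36 (-2.18 ± 0.19), M03D4.4 (-2.07 ± 0.19) and fkh-2 (-2.03 ± 0.21). The frh-1 signal rose by 2.12 ± 0.39 (adjusted p = 0.00035), while it changed by -0.11 ± 0.39 in controls (adjusted p = 0.916). Lysozyme, saposin-like and pathogen response genes had 17 rises, 1 fall and 48 not passing, 22 and 2 when adjusted over the list alone (list adjusted p = 1.57e-05, adjusted p = 0.147 with an estimated correlation). Examples are lys-3 (2.37 ± 0.21) and lys-4 (2.28 ± 0.26). Of the 16 list calls of this contrast by camera, 0 held with an estimated correlation. With that correlation 5 lists had an unadjusted p under 0.05, and fry called 11 lists.

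From day 7 to day 14 the labelled RNAi arm had 2591 rises and 2744 falls. T24A6.7 (4.17 ± 0.24), R03H10.6 (4.12 ± 0.20), ddn-1 (3.75 ± 0.24), Y46H3A.5 (3.72 ± 0.19), F35E12.11 (3.69 ± 0.30), F43C1.7 (3.55 ± 0.27), H02F09.3 (3.52 ± 0.30) and C27H5.6 (3.28 ± 0.17) rose most. The largest falls were in dct-17 (-3.86 ± 0.25), clec-222 (-3.21 ± 0.17), cyp-13A7 (-2.98 ± 0.22), spp-17 (-2.71 ± 0.26), acdh-1 (-2.70 ± 0.46), Y39B6A.1 (-2.69 ± 0.19), nspc-1 (-2.64 ± 0.19) and Y62H9A.4 (-2.62 ± 0.19). The frh-1 signal rose by 3.03 ± 0.39 (adjusted p = 7.09e-07), against -0.34 ± 0.39 in controls (adjusted p = 0.596). HIF-1 targets had 11 rises and 3 not passing, also 11 when adjusted over the list alone (list adjusted p = 2.57e-10, adjusted p = 0.00364 with an estimated correlation). Intracellular pathogen response genes had 26 rises, 2 falls and 21 not passing, 28 and 2 when adjusted over the list alone (list adjusted p = 1.21e-12, adjusted p = 0.0442 with an estimated correlation).

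Set beside the change with age, the day 14 RNAi effect was nearly uncorrelated with the control change from day 4 to day 7 (r = -0.05, rho = 0.04 across genes, contrasts that share no arrays). Of 317 genes that fell with age there and were also called at day 14, 252 were higher in the labelled RNAi arm and 65 lower. Of 284 that rose with age, 208 were higher and 76 lower, where 76.6% of all day 14 calls were higher. The day 4 RNAi effect had r = 0.21 (rho 0.14) with the control change from day 7 to day 14. Of 185 genes rising with age there and called at day 4, 173 were higher in the labelled RNAi arm, and of 289 falling with age 147 were lower and 142 higher, where 74.5% of all day 4 calls were higher.

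**Figure D4:**
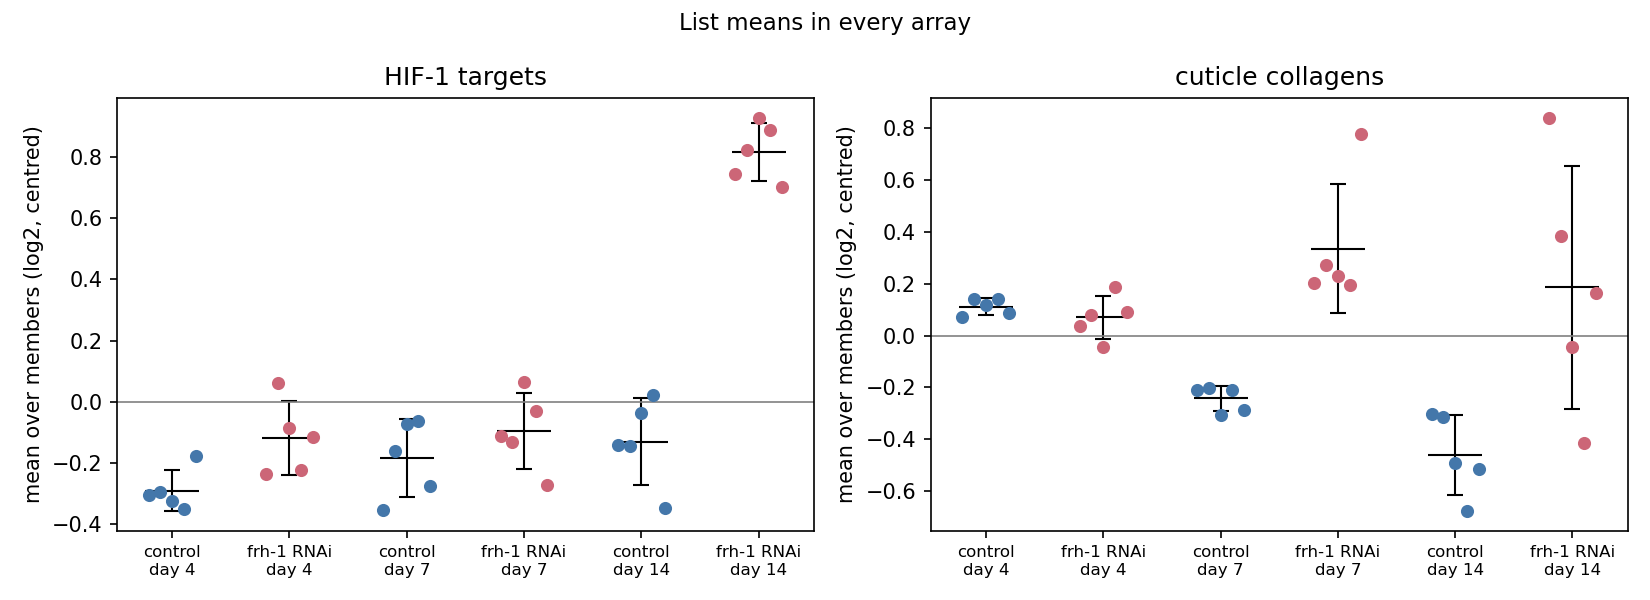
Mean over the members of HIF-1 targets (left) and cuticle collagens (right) in each array, centred per gene (log2, vertical axis) and shown by group, with bars for means and error bars for standard deviations of 5 arrays. HIF-1 targets lie between 0.70 and 0.93 in the labelled RNAi arrays of day 14 and cuticle collagens between -0.41 and 0.84.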

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

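Of the tests in this part, those on exchanged arrays, the chromosome stretch, the trigger RNA, larvae, intestinal genes, other splits of the arrays and the 3 replicate 5 arrays were chosen only after the result was seen.

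The frh-1 signal was higher in the arrays labelled frh-1 RNAi at day 7 and day 14, against what the label of a knockdown implies. Single arrays exchanged between the arms are excluded, since 0 control arrays lie nearer to the other arm's mean at either age, while 1 labelled RNAi array of day 7 (7.64) lies below the midpoint of 7.70. Raised transcription of the whole stretch of chromosome is excluded, because 7 measured neighbours had a median change of 0.02 at day 14, although egl-44 was 0.62 higher at day 7 (adjusted p = 0.00024). RNA of the bacterial trigger construct binding to the frh-1 probes may account for the signal, and it stays open because 0 named probe sets read the bacterial parts of that construct. A complete exchange of the arms and a rise of the worm's own transcript were not tested.

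Of 170 cuticle collagens 44 were called higher in the labelled RNAi arm at day 7 and 55 at day 14 (adjusted p = 0.169 and 0.137 with an estimated correlation), 22 in a fit of day 14 alone, and the means of its day 14 arrays ran from -0.41 to 0.84. The 3 frh-1 RNAi arrays of replicate 5 are excluded as the whole cause, since without them 52 of the 55 collagens called higher at day 14 and 33 of the 44 at day 7 were kept. Larvae among the worms could also carry these transcripts, and this stays open, because the larval molting markers passed at both ages with the preset correlation (adjusted p = 9.42e-07 and 0.0376) and not with an estimated one (largest adjusted p = 0.752), the day 14 call being lost also after quantile normalization (0.0713), without the dimmest genes (0.12) and by fry (0.265). A delay of the change with age stays open too, because the correlation across collagens with the control change from day 4 to day 7 was -0.05 (jackknife standard error 0.094, -0.10 to 0.00 with 1 array left out) while 19 of the 39 collagens that fell in controls were higher at day 14. The low correlation says little on those 39, since most collagens in it did not change with age.

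HIF-1 targets were higher in the labelled RNAi arm at day 14. A single array of day 14 is excluded, because 9 to 11 members were called higher with any 1 of the 10 arrays left out (largest list adjusted p = 5.67e-14). A wider rise of intestinal genes is excluded for the increase after day 7, since the intestine markers had a median difference of 0 there (standard deviation 0.56 over 23 members), below the 0.83 of HIF-1 targets by more than that spread, and the lists share 0 members. For the effect at day 14 itself it stays open, because intestine markers had a median of 0.66 there against 0.75, although at day 7 the medians were 0.68 and -0.05. The mean change of 0.95 was 0.89 after a further quantile normalization and 0.93 after subtracting array medians. Scale differences left between the deposited arrays thus account for little of it. The authors' own normalization stays open, because the values were already normalized and array images were not used. A response of the worms to the treatment stays open too.

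For counts of genes, the arrays were split in 100 ways with the real split included. Only 1 split, the real one, gave as many genes for the RNAi effect at day 4 (816, highest other 20) and day 14 (1996 and 362), and for its difference between days 4 and 14 (588 and 210). So it was for the control changes from day 4 to day 7 (4020 and 667) and from day 7 to day 14 (7292 and 2540), and for those of the labelled RNAi arm (2354 and 1076, 5335 and 1602). Chance can be excluded for these counts other than the difference between days 4 and 14. Its exchanged labels also remove the RNAi effect at both ages. Those splits therefore cannot tell a difference between ages from an equal effect at both. None of these splits was limited to those parting same-numbered arrays. For day 14 and the age changes, where numbers may also pair arrays, the exclusion holds only if they do not.

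At day 7 replicate numbers pair the arrays. There 16 splits part all 5 pairs as the real one does, too few for a share under 0.05, with 2887 genes in the real split and 212 in the highest other. The 84 further splits, which keep some pairs together, reached 554. For counts that hold day 7 beside other ages, 100 splits were drawn with all day 7 pairs parted. For the averaged effect only 1 gave as many (3636 and 569). Labels were exchanged freely at days 4 and 14, so chance can be excluded only if numbers do not pair arrays there. The labels of all 3 ages were exchanged together, so these splits cannot tell an effect at 1 age from one at all 3. For the difference between days 4 and 7, 3 splits gave as many (445 genes, highest other 711). Between days 7 and 14 it was 4 (734 and 2375). The others that reached the real counts all leave the day 7 arms whole and mix another age, so they hold the day 7 effect itself. Splits that mix day 7 reached 194 and 334. Of the 100 drawn, 2 and 9 leave the day 7 arms whole, so these shares, though under 0.05, depend on how many such splits were drawn. The splits therefore cannot decide on chance for these 2 differences.

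In 12 of 142 groups of 5 values 1 array stood far from the other 4 by Dixon's test, where about 1 in 20, or 7.1, would by chance. The frh-1 level was 4.83 in control day 7 replicate 1 and 6.72 to 6.85 in the others. Means over all probe sets were 5.428 (others 5.372 to 5.383), 5.486 (5.370 to 5.392) and 5.475 (5.368 to 5.374) in frh-1 RNAi replicate 5 of days 4, 7 and 14. The col-125 level, rounded, was 12 in frh-1 RNAi day 7 replicate 5 (others 10.12 to 10.53) and 7.59 in control day 7 replicate 4 (6.70 to 6.96). Further such levels were cyp-14A3 at 4.05 in frh-1 RNAi day 7 replicate 4 (lowest of the others 2.81), lips-11 at 8.0 in frh-1 RNAi day 14 replicate 4 (6.38 to 6.64) and cyp-13A7 at 4.07 in control day 7 replicate 1 (3.19 to 3.37). In controls of day 14, C17H12.8 was 7.47 in replicate 1 (8.42 to 8.74) and F53H4.2 was 10.55 in replicate 2 (9.48 to 9.67). The mean over cuticle collagens was 0.78 in frh-1 RNAi day 7 replicate 5 (0.19 to 0.27).

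Differences of the RNAi effect between ages that passed the test were, for day 7 against day 4, col-94 3.52, B0024.4 3.00, col-160 2.79, F42A10.7 2.69, tts-2 2.67, frh-1 2.22, cyp-14A3 -3.01, far-3 -2.94, F48C1.9 -2.74, col-183 -2.73 and cyp-13A8 -2.49. The F42A10.7 and frh-1 differences were lost without any of 15 and 7 single arrays, which the report names. For day 14 against day 7 they were irg-4 3.42, frh-1 3.37, C14C6.5 3.33, cyp-14A3 2.79, clec-52 2.56, cyp-13A7 -3.26, B0205.13 -2.76, B0024.4 -2.70, tts-2 -2.70 and acdh-2 -2.55. For day 14 against day 4 they were frh-1 5.60, C14C6.5 3.96, clec-52 3.52, pud-4 3.37, asm-3 3.24, cyp-13A7 -4.70, B0205.13 -4.33, cyp-13A8 -4.32, cyp-14A4 -4.07 and cdr-4 -3.81. List medians for day 7 against day 4 were -0.21 for cytochrome P450 genes, -0.31 for metallothionein and cadmium response, -0.20 for germline and oocyte markers, 0.40 for cuticle collagens and 0.59 for intestine markers. For day 14 against day 7 they were 0.83 for HIF-1 targets and -0.40 for synaptic and neuronal markers. For day 14 against day 4 they were 0.70 for HIF-1 targets, -0.08 for cytochrome P450 genes, 0.27 for the propionate shunt, 0.40 for cuticle collagens and 0.54 for intestine markers. Of these list calls, those of cuticle collagens were lost with an estimated correlation (adjusted p = 0.0835 for day 7 and 0.126 for day 14 against day 4).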

How the results depend on the processing

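Leaving out the 3 labelled RNAi arrays of replicate 5 was added after the result was seen. Of 465 named gene calls, 66 were lost with at least 1.5-fold changes and 42 with adjusted p under 0.01, and 41 of 436 in fits of only the groups compared. Of the 465, 457 held after quantile normalization, 449 after subtracting array medians, 464 with the replicate block and 444 without those 3 arrays. With 1 array left out, 5706 of 5900 held. These calls were chosen for large changes or small p, so their stability says little about other calls. List results changed most with the estimated correlation, where 196 of 240 calls were lost. The cause was not tested. Where a count moved by over 1.5 times, the values are these. Array weights gave 755 genes for the difference between days 4 and 7. Fitting only the groups compared gave 1136 at day 14. With at least 1.5-fold changes there were 524, 1460 and 1031 genes at days 4, 7 and 14 and 767 averaged, 1934 and 3354 for the control age changes and 1427 and 2532 for those of the labelled RNAi arm. With adjusted p under 0.01 there were 510, 1671, 987 and 2276 for the RNAi effects and their average, 154, 231 and 293 for the differences between days 4 and 7, 7 and 14, and 4 and 14, and 2578 and 1431 for the changes from day 4 to day 7 in control and labelled RNAi. The difference between days 7 and 14 ranged from 459 without frh-1 RNAi day 7 replicate 3 to 887 without replicate 4 of that group. With an estimated correlation the lists past the threshold numbered 5, 2 and 6 at days 4, 7 and 14, 11 averaged, 4, 2 and 4 for the differences, 5 and 3 for control and 0 and 2 for labelled RNAi age changes. Fry called 12, 6 and 10 lists for the differences. Without detection calls, levels under 3.23, the lower quartile of the gene means, are not known to lie above background. Such was the lower level for F22B3.7 at days 4 and 7, cyp-14A3 and hrg-3 at day 7, ilys-2, msp-38 and msp-78 at day 14, and col-93 and C54F6.15 with age in controls, so the sizes of these changes are uncertain. The mitochondrial ribosomal proteins, not called as deposited for the averaged effect, had a mean of -0.05 after quantile normalization (adjusted p = 0.0399), opposite in sign.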

Other observations

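Iron and heme genes were looked at in the labelled RNAi arm. The intestinal ferritin gene ftn-1 fell at day 7 (-1.19 ± 0.21, adjusted p = 0.000197, n = 5 per group) and stood at 0.02 ± 0.21 at day 4 and 0.16 ± 0.21 at day 14. The other ferritin gene, ftn-2, fell at day 4 (-0.48 ± 0.078), and the metal transporter gene smf-3 rose at day 14 (0.81 ± 0.19). Of 8 heme transport genes, hrg-9 rose at day 4 (0.98 ± 0.18) and 7 did not pass, 3 when adjusted over the list alone (list adjusted p = 0.000109, adjusted p = 0.138 with an estimated correlation). At day 7, 4 of the 8 rose, 6 when adjusted over the list alone (list adjusted p = 0.000759, adjusted p = 0.233 with an estimated correlation), with hrg-3 at 1.39 ± 0.29. At day 14, 2 of the 8 rose, also 2 when adjusted over the list alone (list adjusted p = 0.0322, adjusted p = 0.515 with an estimated correlation). That list call was also lost by fry (0.11), with array weights (0.0523), without the dimmest genes (0.067) and without the replicate 5 arrays (0.0775). Of 9 iron homeostasis genes 3 rose at day 14 and 6 did not pass, also 3 when adjusted over the list alone (list adjusted p = 0.0447, adjusted p = 0.118 with an estimated correlation), a list call also lost after quantile normalization (0.0806), with the replicate block (0.0542) and without the dimmest genes (0.067). Only 1 of the 3 rose in a fit of the day 14 arrays alone. Among delta-9 desaturase genes, fat-5 fell at day 4 (-1.69 ± 0.30) and day 14 (-1.19 ± 0.30), and fat-7, which fell at day 4, did not pass at day 14 (-0.54 ± 0.43, adjusted p = 0.532).

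Of 75 ribosomal protein genes, 15 fell in controls from day 4 to day 7, 19 when adjusted over the list alone (list adjusted p = 1.91e-11, adjusted p = 0.455 with an estimated correlation). These 15 were 8 without control day 4 replicate 5, 23 with the replicate block, 25 after quantile normalization and 27 with a variance trend. From day 7 to day 14, 27 rose, 30 when adjusted over the list alone (list adjusted p = 7.93e-09, adjusted p = 0.343 with an estimated correlation), and rpl-11.2 went from -0.59 ± 0.085 in the first interval to 1.22 ± 0.085 in the second. The 27 rises were 55 after quantile normalization and 15 after subtracting array medians. Of 32 proteasome genes 18 fell and 1 rose in the later interval, 23 and 1 when adjusted over the list alone (list adjusted p = 6.15e-05, adjusted p = 0.343 with an estimated correlation). Their 18 falls were 10 without control day 14 replicate 1, 8 after quantile normalization and 11 in a fit of the compared groups alone. Of 277 nuclear hormone receptor genes 75 rose and 15 fell there, 76 and 15 when adjusted over the list alone (list adjusted p = 1.33e-05, adjusted p = 0.0696 with an estimated correlation), with nhr-85 at 2.18 ± 0.10.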
